A study of Mus musculus with 39 samples.

How the data were processed

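The series measured messenger RNA by RNA sequencing in YFP-positive tumour cells sorted from mouse pancreatic tumours. Per the labels' protocols, tumour cell clones classed as T cell low or T cell high were implanted under the skin of C57BL/6 mice, and tumours were taken 3 weeks later without treatment. RNA was extracted with a column kit for small samples and libraries were made with an NEB RNA-seq kit and sequenced on an Illumina NextSeq instrument. Clones are named as in the titles, which hold the number of a parent tumour line followed by c and a clone number, so yfp_6499c3 and yfp_6499c4 are read as 2 clones of one line. The number that ends a title is called the tumour number here.

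The deposited table held raw counts, as whole numbers, for 39017 genes in 39 libraries. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on the mm10 genome. The versions, the annotation release and the strand setting of the authors' counting are not given in the sources used here. Reads from overlapping or antisense genes may therefore have been counted for a neighbour, and members of the H2, Akr1c and haemoglobin families share near-identical sequence, so their counts are uncertain. Coordinates are from GENCODE M21 on GRCm38, in which 37693 of the gene identifiers were found. For 214 repeated symbols, the row with the highest total was used.

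Groups came from the labels: 18 libraries of 9 T cell low clones, 14 libraries of 6 T cell high clones, 4 libraries of 2 intermediate clones, and 3 libraries of 3 clones with no class, which entered no comparison. The labels do not say that libraries of a clone came from separate animals. The counts of a clone were therefore summed and the clone was the replicate, so p-values at the clone level measure the spread between these sums. Over all libraries the sums include libraries that closely resemble those of other clones. Their spread may therefore be smaller than that between the clones. Clones of one parent line, such as yfp_6419c1, yfp_6419c4 and yfp_6419c5, were taken as separate replicates. The fits and permutations treat such clones as independent, which they may not be. P-values within parent lines measure only the spread between libraries, which may be technical. Totals ranged from 7638130 to 103794674 counts per library, with a median of 34565903. Intervals and standard errors that rest on one library would cover counting error only, and none is used.

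Genes were kept with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. T cell high and low clones were compared in one fit of 15 clones. Clones of the 2 parent lines that held both classes were compared per library with the line as a block. Intermediate clones were compared in one fit of 17 clones. Levels are given as CPM (counts scaled to a common library total) with TMM factors, as mean ± SD over clones, and fold changes as log2 with the standard error of the fit.

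For 39 gene lists, of which 12 hold markers of other cell types that a sort could let through, the score of a clone was the mean log2 CPM of the measured members with a prior count of 2. The difference in score was tested with a two-sided exact permutation test over all splits of the clones, adjusted over the lists with 3 or more measured members. Named genes were, in each direction, the 10 with the smallest p among those that passed with a mean of at least 5 CPM, or the 5 with the smallest p where fewer than 5 passed. The rule passed over Riken, Gm and pseudogene symbols, and added 30 candidates and 2 to 4 members per list. Some of these genes are not reported here. For other comparisons it took genes that passed. The clone as the replicate, the tests, the lists, the candidates and the alternatives of scaling, filter, replicate, covariate and threshold, including DESeq2 1.42.0 and limma 3.58.1, were fixed before the data were examined.

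The division of libraries by heart transcripts was chosen after seeing the data. The CPM of the heart genes Myh6, Myh7, Myl2 and Mb, and of the liver genes Alb, Fga, Fgb, Ahsg, Mat1a and Cps1, were summed, and libraries with a heart sum under 10 CPM were called heart-free. Each comparison was run again in heart-free libraries. The 5 genes per direction with the smallest p in the heart-free comparison are named by the same rule.

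The steps were tested on simulated data with 200 changed genes, 100 per fold size, drawn from genes with a mean of at least 5 CPM. Genes were simulated independently of each other. Neither sister clones nor heart transcripts were modelled, so recovery in the real data may be lower. In the clone comparison over 18551 genes, 73% of genes changed by log2 1 and 88% of those changed by log2 2 were recovered, and 3.59% of calls were false. The shares recovered were 51% and 91% over 15635 genes of the heart-free libraries, 32% and 77% over 20028 genes for intermediate against low, and 1% and 44% over 16045 genes within parent lines. In the same order, 3.40%, 7.63% and 10% of calls were false. Changes smaller than log2 1 were not simulated. With shuffled lists, 3.5% of 200 gave an unadjusted permutation p under 0.05. Figures were drawn with matplotlib 3.10.9.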

Results

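RNA sequencing counts were obtained for 39 libraries of sorted tumour cells from subcutaneous mouse pancreatic tumours grown from 20 tumour cell clones. The design asked which genes differ in expression between tumour cells of T cell low and T cell high tumours. T cell low was the class of 18 libraries from 9 clones, and T cell high of 14 libraries from 6 clones. A further 4 libraries from 2 clones were of an intermediate class, and 3 libraries had no class. Library totals ran from 7638130 to 103794674 counts in low and from 19774638 to 55997777 counts in high libraries, with the lowest and the highest total in low libraries.

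The libraries fell into 2 kinds by transcripts of heart and liver. In 19 of the 39, the summed level of the heart genes Myh6, Myh7, Myl2 and Mb was 152 to 4893 CPM, and the liver gene Alb, which encodes serum albumin, stood at 220.4 to 7321 CPM. In the other 20 the heart sum was at most 0.235 CPM. The log2 ratio of liver to heart transcripts was 1.66 ± 0.07 (SD, n = 19) over the libraries that held them. Of the 19 libraries, 18 carried tumour number 1 in their title, against 1 of the other 20 (2-sided Fisher's exact test, p = 5.82e-09). Heart transcripts were found in 9 of 18 low and 6 of 14 high libraries (2-sided Fisher's exact test, p = 0.735). That test covers presence only, and the amounts were uneven. Where present, the heart sum was 2553 to 4872 CPM in high libraries. In low libraries it was 152 to 4893 CPM, with 152, 568, 741, 1799 and 1954 CPM below the high range. Comparisons over all libraries therefore cannot fully separate class from the amount of these transcripts. The first principal component held 72.5% of the variance and separated the 2 kinds. Only 7 of the 34 libraries of clones with several libraries correlated best with their own clone, against 5 of 5 among such heart-free libraries. No pair of libraries agreed within counting noise. The closest pair, yfp_6499c4 tumour 1 and yfp_6419c5 tumour 1, differed by a chi-square of 3.41 per degree of freedom. The closest pairs were all heart-bearing libraries of different clones. In that closest pair Krt19 was at 1073 and 1085 CPM and C1qa at 143 and 148 CPM. In tumour 2 of the same clones, which was heart-free, Krt19 was at 2926 and 1706 CPM and C1qa at 418 and 7.34 CPM. Levels over all libraries may therefore not be those of the clone alone, and their SDs, standard errors and p-values may not measure the spread between clones. The SD of the pan-leukocyte score over high clones was 0.43 with all libraries and 1.48 with heart-free ones. Over low clones it was 1.13 and 1.06.

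**Figure D1:**
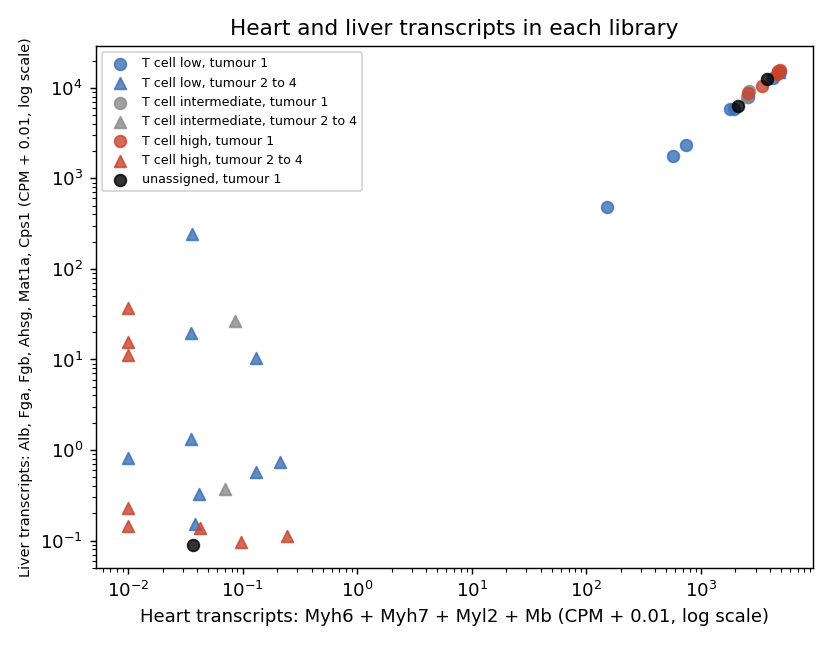
Summed heart transcripts (x axis, CPM, log scale) against summed liver transcripts (y axis, CPM, log scale) in each of the 39 libraries, by class (colour) and by tumour number (circles for 1, triangles for 2 to 4), with 0.01 CPM added. The 19 libraries at the upper right lie on a line, with heart sums of 152 to 4893 CPM.

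In T cell high clones, some epithelial genes such as Cldn7 stood higher than in T cell low clones and the prostaglandin enzyme gene Ptgs2 stood lower, but no single gene passed the test between clones. The epithelial genes Cdh1 and Krt8 differed by -0.01 ± 0.18 and -0.11 ± 0.20. Cldn7, a tight junction gene (ENSMUSG00000018569, chromosome 11, 69964779 to 69967885), was at 90.8 ± 52.5 against 18.2 ± 8.22 CPM (mean ± SD, n = 6 and 9 clones), a log2 difference of 2.32 ± 0.40 (SE, adjusted p = 0.110). Ptgs2, which encodes cyclooxygenase 2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), was at 50.8 ± 8.85 against 122 ± 39.7 CPM, a log2 difference of -1.26 ± 0.21 (adjusted p = 0.103). Of 18551 genes tested with edgeR, 0 were called higher and 0 lower, with 2176 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.103. DESeq2 called 80 genes higher and 43 lower on the same sums, and limma on clone means called 0, with 1486 genes at an unadjusted p under 0.05. With each library as a replicate and heart transcripts as a block, edgeR called 58 higher and 69 lower, though libraries of a clone are not independent. Fits of clones within heart-free and within heart-bearing libraries each called 0, with 2095 and 1851 genes at an unadjusted p under 0.05. Without clone yfp_2838c3, the edgeR count was 12 higher and 4 lower, the latter being Bmf, Snx27, Ankrd13c and Zfp516, named after their values were seen. Without yfp_6421c2 only Ptgs2 was called, as lower, and the count at an unadjusted p under 0.05 was 1429 without yfp_7160c2 and 1444 without yfp_6555c3.

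The other genes with the smallest p in each direction did not pass either. Trpv4, a calcium-permeable channel gene (ENSMUSG00000014158, chromosome 5, 114622152 to 114658421), was at 32.4 ± 20.1 against 7.58 ± 2.80 CPM and differed by 2.10 ± 0.35. Stmn2, a microtubule-regulating stathmin gene (ENSMUSG00000027500, chromosome 3, 8509360 to 8561606), was at 35.3 ± 40.9 against 2.46 ± 1.61 CPM and differed by 3.85 ± 0.71. Also higher were the glutathione transferase gene Gstt2 (ENSMUSG00000033318, chromosome 10, 75831114 to 75837424) at 1.84 ± 0.37 and the tyrosine kinase gene Fes (ENSMUSG00000053158, chromosome 7, 80377756 to 80387946) at 1.05 ± 0.22. On the lower side, Tex2 (ENSMUSG00000040548, chromosome 11, 106502147 to 106613423) was at 50.7 ± 3.38 against 72.1 ± 7.99 CPM and differed by -0.51 ± 0.09. The transcription elongation factor gene Ell2 (ENSMUSG00000001542, chromosome 13, 75706757 to 75772364) differed by -0.56 ± 0.12. The cAMP phosphodiesterase gene Pde7a (ENSMUSG00000069094, chromosome 3, 19223108 to 19311322) differed by -0.45 ± 0.10, and the vesicle tethering gene Vps54 (ENSMUSG00000020128, chromosome 11, 21239281 to 21321136) by -0.32 ± 0.07. These genes were chosen for their small p in the same clones, so a separation of the classes follows in part from the choice. It was not counted over all genes, and the heart-free libraries are part of the same data. All 6 high clones lay below every low clone for Tex2, Pde7a and Vps54. For Cldn7, Trpv4, Stmn2 and Gstt2, 5 of 6 lay above every low clone. Adjusted p was 0.103 for Tex2 and Trpv4, 0.157 for Stmn2 and 0.265 for Vps54. Each high clone was also above every low clone for H2-M2, a gene under the level minimum of the rule (adjusted p = 0.103). In heart-free libraries, 6 of 6 high clones lay beyond every low clone for Tex2 and Vps54, 5 for Pde7a, Cldn7 and Gstt2, and 4 for Trpv4, Stmn2 and H2-M2. There, yfp_6556c4 was at 0.212 CPM for H2-M2 and 0.319 CPM for Stmn2, against up to 1.69 and 1.37 CPM in low clones. In libraries with heart transcripts alone, the differences were 1.17 for Cldn7, -0.87 for Ptgs2, 1.13 for Trpv4 and -0.19 for Tex2, each with an adjusted p of 0.4655. With the clone yfp_2838c3 left out, Cldn7 differed by 2.53 and Trpv4 by 2.29, and both passed (adjusted p = 0.0136). With each other clone left out neither passed, at an adjusted p of up to 0.309 for Cldn7 and 0.277 for Trpv4.

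**Figure D2:**
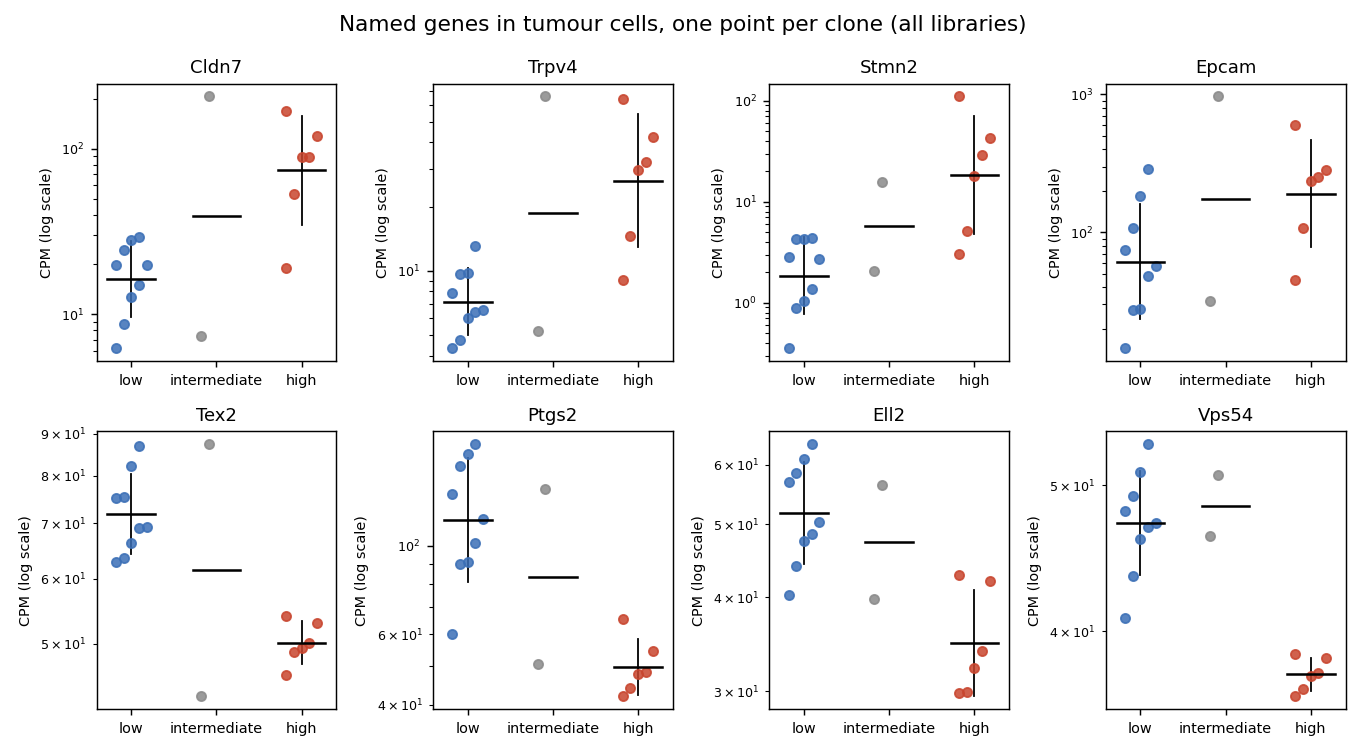
Levels of 8 named genes (y axes, CPM, log scale) with one point per clone, by T cell class. Horizontal lines are geometric means and vertical lines 1 SD of log2 CPM for the 9 low and 6 high clones, and the 2 intermediate clones have a mean only. For Tex2 and Vps54, which were chosen for their small p in these clones, all 6 high clones lie below every low clone.

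None of the 30 candidate genes passed, of which Ptgs2 came closest. Among chemokine and growth factor genes, the neutrophil attractants differed by Cxcl1 at -0.83 ± 0.47, Cxcl2 at 0.05 ± 0.52 and Cxcl5 at -0.42 ± 0.36, and the colony-stimulating factors by Csf1 at -0.05 ± 0.30, Csf2 at -0.29 ± 0.75 and Csf3 at 0.66 ± 0.43. The monocyte attractant Ccl2 differed by -0.07 ± 0.38, and the lymphocyte attractants by Cxcl9 at 0.72 ± 0.77, Cxcl10 at -0.31 ± 0.37, Cxcl16 at 0.12 ± 0.17 and Ccl5 at 0.44 ± 0.48. Ccl5 was at 0.966 ± 0.512 against 0.709 ± 0.562 CPM. The transcription factor gene Myc was at 128 ± 27.4 against 177 ± 116 CPM (-0.47 ± 0.30), the inhibitory ligand gene Cd274 at 11.6 ± 1.94 against 12.1 ± 6.81 CPM (-0.05 ± 0.28) and Tgfb1 differed by -0.10 ± 0.27. Antigen presentation and interferon genes differed by B2m at -0.09 ± 0.37, H2-K1 at 0.06 ± 0.40, Tap1 at 0.42 ± 0.44, Cd74 at 1.0 ± 0.46 and Irf1 at 0.14 ± 0.12. Of the cell identity genes, Epcam was at 256 ± 194 against 91.8 ± 90.2 CPM (1.48 ± 0.62), and the others differed by Cdh1 at -0.01 ± 0.18, Krt19 at 0.09 ± 0.21, Vim at -0.35 ± 0.21, Zeb1 at -0.32 ± 0.16, Pdx1 at -0.66 ± 0.23 and Gata6 at -0.29 ± 0.19. The tumour suppressor genes Cdkn2a and Trp53 differed by 0.22 ± 0.61 and -0.41 ± 0.19. Adjusted p of the candidates other than Ptgs2 was 0.349 for Pdx1 and higher for the rest, up to 0.982 for Cdh1.

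Of the 39 gene lists, none passed the exact permutation test over lists, and 4 had an unadjusted p under 0.05. The list with the smallest p was the epithelial one, with a score of 6.85 ± 0.50 in 6 high and 6.00 ± 0.41 in 9 low clones, a difference of 0.86 (exact p = 0.00280), with an adjusted p of 0.109. Of its 14 measured members, 0 passed over all genes and 6 passed higher when adjusted over the list alone, and 12 had a positive fold change. Those 6, named after their values were seen, were Cldn7 at 2.32 ± 0.40, Rab25 at 2.15 ± 0.50, Ocln at 0.69 ± 0.22, Cldn4 at 1.57 ± 0.50, Esrp1 at 2.17 ± 0.78 and Krt7 at 0.71 ± 0.27. The keratins with the highest levels besides Krt7 differed little, with Krt8 at -0.11 ± 0.20, Krt18 at 0.10 ± 0.19 and Krt19 at 0.09 ± 0.21. With a clone left out in turn, the adjusted p of the epithelial list ran from 0.0195 without yfp_2838c3, where alone it passed, to 0.312 without yfp_7160c2. With camera and a preset correlation, 11 lists were called higher and 4 lower, and with an estimated correlation 0 were called, with an adjusted p = 0.860 for the epithelial list.

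The other lists with an unadjusted p under 0.05 were MHC class II presentation, Wnt targets and proliferation. MHC class II presentation, the display of antigen to helper T cells, differed by 1.25 (exact p = 0.0328), with H2-Ab1 at 1.20 ± 0.48, H2-Eb1 at 1.19 ± 0.50 and H2-Aa at 0.96 ± 0.52, and all 7 members had a positive fold change. Wnt targets differed by 0.73 (exact p = 0.0296), with Lgr5 at 1.0 ± 0.47, Rnf43 at 0.40 ± 0.31, Znrf3 at -0.14 ± 0.13 and Tcf7 at -0.19 ± 0.24. Proliferation genes differed by -0.38 (exact p = 0.0414), with 0 of 24 members positive, among them Top2a at -0.54 ± 0.21, Mki67 at -0.39 ± 0.17, Pcna at -0.27 ± 0.13 and Mcm6 at -0.31 ± 0.19. Adjusted over the list alone, 1 proliferation gene, Tyms (-0.38 ± 0.10), 1 inhibitory gene, Ptgs2, and 3 pancreatic duct genes passed, of which Cftr (1.96 ± 0.58) and Agr2 (2.63 ± 0.83) were higher and Pdx1 lower, and no class II or Wnt gene did. Camera with a preset correlation called the class II and Wnt lists higher and proliferation lower, and with an estimated correlation the adjusted p = 0.860 for each.

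Over all libraries, markers of other cell types stood higher in T cell high clones without passing. They could have come through the sort or together with the heart and liver transcripts. The pan-leukocyte score differed by 0.75 (exact p = 0.115), with Coro1a at 0.67 ± 0.41, Tyrobp at 0.61 ± 0.40 and Laptm5 at 0.50 ± 0.43. Macrophage markers differed by 0.82 (exact p = 0.151), with C1qa at 0.84 ± 0.47, Lyz2 at 0.69 ± 0.39 and C1qc at 0.75 ± 0.49. T cell markers differed by 0.91 (exact p = 0.155), with Cd3e at 0.83 ± 0.59, Cd4 at 0.72 ± 0.58 and Cd6 at 0.50 ± 0.69. Their levels were very low, with a mean score of -0.85 in high and -1.77 in low clones. Neutrophil markers differed by 0.71 (exact p = 0.191), with Csf3r at 0.45 ± 0.46, S100a9 at -0.28 ± 0.70 and S100a8 at -0.09 ± 0.64. Dendritic cell markers differed by 0.55 (exact p = 0.151), with Itgax at 0.82 ± 0.41 and Cd209a at 0.66 ± 0.61. B cell markers differed by 0.45 (exact p = 0.294), with Blk at 1.59 ± 0.59. Cytotoxic and NK cell markers differed by 0.30 (exact p = 0.495), with Gzmb at -0.88 ± 0.69 and Klrk1 at 0.69 ± 0.62. Fibroblast markers differed by 0.50 (exact p = 0.297), with Col1a2 at 1.01 ± 0.48, Dcn at 0.64 ± 0.39 and Col1a1 at 0.66 ± 0.54. Endothelial markers differed by 0.92 (exact p = 0.109), with Plvap at 0.55 ± 0.38, Cdh5 at 0.59 ± 0.42 and Pecam1 at 0.63 ± 0.48. Red blood cell markers differed by 0.84 (exact p = 0.243), with Hbb-bs at 0.33 ± 0.56 and Hba-a1 at 0.31 ± 0.54. Skeletal muscle markers differed by 1.35 (exact p = 0.0697), with Tnni2 at 0.48 ± 0.27 and Tnnt3 at 0.84 ± 0.55. Adipocyte markers differed by 0.28 (exact p = 0.603), with Adipoq at 0.32 ± 0.37 and Cidec at -0.27 ± 0.46. Clone yfp_6419c4 had 1 library, a heart-free one, and without it the difference was 0.42 for the pan-leukocyte score, 0.49 for macrophage, 0.61 for endothelial, 0.45 for red blood cell, 0.23 for B cell and -0.00339 for adipocyte markers. For fibroblast markers it was 0.21 without yfp_6555c3, and for cytotoxic and NK cell markers 0.11 without yfp_6499c3. Camera with a preset correlation called the pan-leukocyte, T cell, macrophage, neutrophil, endothelial and skeletal muscle lists higher, and the adjusted p = 0.860 for each with an estimated correlation. In heart-free libraries, 2 of 12 T cell, 0 of 10 cytotoxic and NK cell, 1 of 7 B cell and 2 of 5 adipocyte markers were measured. These lists could not be tested there, and Cd3e was at most 0.773 CPM. In the same libraries, fibroblast markers differed by -0.19 (exact p = 0.840), skeletal muscle markers by -0.12 (exact p = 0.669) and endothelial markers by 0.28 (exact p = 0.728). There yfp_6555c3, with 1 such library, had a fibroblast score of 7.44 and an endothelial score of 4.07. The other high clones had 1.60 to 3.00 and -0.160 to 1.04, so both differences depend on this clone. Neutrophil markers differed there by 1.03 (exact p = 0.169), red blood cell markers by 0.80 (exact p = 0.324) and dendritic cell markers by 0.60 (exact p = 0.239). The neutrophil score of yfp_6555c3 was 3.55 and its dendritic cell score 1.998, against -0.147 to 1.66 and -1.65 to 0.806 in the other high clones. Its red blood cell score was 2.55, with 2.31 in yfp_2838c3 and -1.15 to 0.833 in the remaining high clones. These differences therefore also depend in part on yfp_6555c3.

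In the remaining lists no member passed over all genes, and each score differed by less than the larger of the 2 SDs between clones. Among lists of cell identity, mesenchymal genes differed by 0.05 (exact p = 0.807), with Vim at -0.35 ± 0.21, Fn1 at -0.46 ± 0.30, Axl at -0.14 ± 0.20 and Sparc at 0.19 ± 0.35. Pancreatic duct and progenitor genes differed by 0.26 (exact p = 0.171), with Spp1 at -0.63 ± 0.27, Muc1 at -0.19 ± 0.41 and Sox9 at 0.17 ± 0.39. Basal and squamous genes differed by 0.07 (exact p = 0.756), with Krt15 at -0.57 ± 0.43 and Krt14 at 0.14 ± 0.82. Acinar genes differed by 0.15 (exact p = 0.221), with Bhlha15 at -0.10 ± 0.30 and Cela1 at 0.10 ± 0.43. Among immune lists, MHC class I presentation differed by 0.49 (exact p = 0.161), with H2-D1 at 0.22 ± 0.26 and Tapbp at 0.04 ± 0.17. The interferon gamma response differed by 0.27 (exact p = 0.417), with Psme2 at 0.14 ± 0.12 and Psme1 at 0.12 ± 0.12. The type I interferon response differed by -0.07 (exact p = 0.866), with Bst2 at -0.34 ± 0.25 and Ifi27 at -0.41 ± 0.32. Myeloid attractants differed by 0.12 (exact p = 0.663), with Il33 at -0.69 ± 0.29 and Il1b at 0.69 ± 0.51. Lymphocyte attractants differed by 0.49 (exact p = 0.234), with Cx3cl1 at -0.20 ± 0.32 and Ccl3 at -0.07 ± 0.60. Inhibitory ligands and enzymes differed by 0.09 (exact p = 0.489), with Arg1 at 0.70 ± 0.32, Cd47 at -0.29 ± 0.15 and Nt5e at -0.41 ± 0.35. NF-kB targets differed by -0.06 (exact p = 0.659), with Nfkb1 at -0.27 ± 0.14 and Vcam1 at -0.46 ± 0.38. Complement differed by 0.67 (exact p = 0.104), with C4b at 0.64 ± 0.44 and C3 at 0.07 ± 0.48. The median fold change of the members was negative, against a positive difference in score, for the mesenchymal (-0.27), duct (-0.13), basal (-0.05), myeloid attractant (-0.09) and inhibitory (-0.05) lists, and for adipocyte markers (-0.16).

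Among lists of growth and metabolism, MYC targets differed by -0.19 (exact p = 0.104), with 0 of 22 members positive, such as Hspd1 at -0.28 ± 0.16, Npm1 at -0.23 ± 0.19 and Ncl at -0.18 ± 0.17. Glycolysis genes differed by -0.24 (exact p = 0.125), with 0 of 14 positive, such as Ldha at -0.35 ± 0.16 and Gapdh at -0.37 ± 0.23. Hypoxia genes differed by -0.23 (exact p = 0.274), with Ndrg1 at -0.49 ± 0.29 and Vegfa at -0.22 ± 0.22. The p53 targets differed by 0.09 (exact p = 0.276), with Perp at 0.35 ± 0.17 and Cdkn1a at 0.09 ± 0.21. MAPK output differed by -0.06 (exact p = 0.774), with Hbegf at -0.37 ± 0.38 and Ccnd1 at 0.10 ± 0.13. TGF-beta targets differed by -0.06 (exact p = 0.653), with Ski at -0.16 ± 0.19. YAP targets differed by 0.07 (exact p = 0.646), with Cyr61 at -0.75 ± 0.27 and Ankrd1 at 0.53 ± 0.22. Oxidative phosphorylation differed by 0.01 (exact p = 0.812), with Atp5a1 at -0.12 ± 0.10 and Sdha at -0.05 ± 0.11. Cholesterol synthesis differed by -0.05 (exact p = 0.680), with Cyp51 at -0.20 ± 0.11 and Hmgcs1 at -0.15 ± 0.18. The unfolded protein response differed by 0.11 (exact p = 0.0723), with Hspa5 at 0.10 ± 0.10 and Calr at -0.07 ± 0.14. Dissociation stress genes differed by 0.06 (exact p = 0.729), with Jun at 0.09 ± 0.28 and Fos at 0.03 ± 0.27. Camera with a preset correlation called MHC class I presentation and complement higher, and MYC targets, glycolysis and hypoxia lower, with an adjusted p = 0.860 for each with an estimated correlation.

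In heart-free libraries, which held 8 libraries of 6 high and 9 libraries of 8 low clones, the epithelial and MHC class II scores again stood higher in T cell high clones, and no gene or list passed. Cldn7 was at 137 ± 89.2 against 15.4 ± 11.9 CPM, a log2 difference of 3.15 ± 0.64, and Cd74, the invariant chain of class II molecules, at 276 ± 159 against 71.3 ± 62.6 CPM, a log2 difference of 1.95 ± 0.59 (adjusted p = 0.149 and 0.247). The epithelial score differed by 1.09 (exact p = 0.00599), with an adjusted p of 0.108 and 2 of 14 members, Cldn7 and Rab25, passing when adjusted over the list alone. The class II score differed by 2.16 (exact p = 0.00633), with an adjusted p of 0.108 and 6 of 7 members passing higher when adjusted over the list alone (H2-Ab1, H2-Eb1, Cd74, H2-DMa, H2-Aa and H2-DMb1). Over their own lists, Cftr, the p53 target Phlda3, the complement inhibitor gene Serping1 and the leukocyte gene Cytip also passed, named after their values were seen. Camera with a preset correlation called these 2 and 5 other lists higher and proliferation lower, and with an estimated correlation the adjusted p = 0.630 for both and 0.901 for the others. The pan-leukocyte score differed by 1.36 (exact p = 0.0686) and the macrophage score by 1.35 (exact p = 0.174) beside them. Lymphocyte attractants differed by 0.72 (exact p = 0.0243), and Wnt targets by 0.80 (exact p = 0.0420). Of 34 lists tested, none passed. With a clone left out in turn, the adjusted p of the epithelial list ran from 0.0264 without yfp_2838c3 to 0.330 without yfp_7160c2. That of lymphocyte attractants ran from 0.0396 without yfp_6556c3 to 0.667 without yfp_6555c3, and each list passed only at its lowest.

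The gene with the smallest p in heart-free libraries was Tex2, at 46.4 ± 4.30 against 74.9 ± 8.84 CPM and a log2 difference of -0.69 ± 0.10 (adjusted p = 0.0973), with all 6 high clones below all 8 low clones. The others with the smallest p were Mphosph8 at 0.65 ± 0.12, Trpv4 at 2.60 ± 0.47, Serpinb5 at 1.11 ± 0.22, Casp8 at 0.48 ± 0.10 and AI661453 at 0.96 ± 0.17 on the higher side, and Dusp18 at -0.94 ± 0.18, Abcc5 at -1.01 ± 0.21, Zzz3 at -0.53 ± 0.11 and Ube3c at -0.47 ± 0.10 on the lower side. Ptgs2 differed by -1.57 ± 0.49 (adjusted p = 0.251), Cxcl1 by -1.44 ± 0.97 and Epcam by 1.64 ± 0.80. Of 15635 genes tested with edgeR, 0 were called, with 2095 at an unadjusted p under 0.05, while DESeq2 called 180 higher and 119 lower. Without clone yfp_2838c3, edgeR called 19 higher and 18 lower, and without yfp_6694c2 it called 1 higher, Tmod1, which is named after its value was seen.

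**Figure D3:**
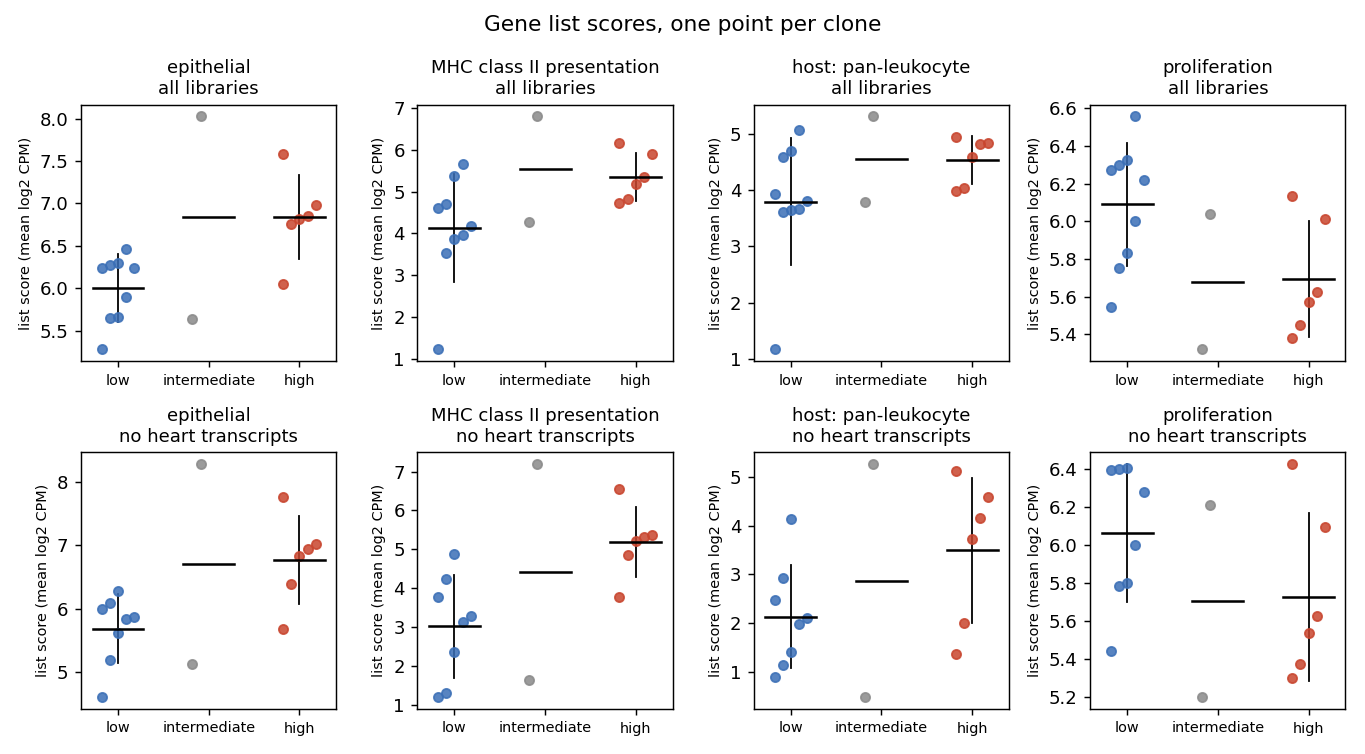
Scores of 4 gene lists (y axes, mean log2 CPM of the members) with one point per clone, by T cell class, over all libraries (upper row) and over heart-free libraries (lower row). Horizontal lines are means and vertical lines 1 SD for low and high clones, and the 2 intermediate clones have a mean only. The epithelial score differed between high and low by 0.86 in the upper row and 1.09 in the lower row, with overlap between clones.

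Within the 2 parent lines that held both classes, some epithelial genes stood higher in the T cell high clone than in its T cell low sister, and no gene passed. Epcam, an epithelial adhesion gene (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129), differed by 3.12 ± 0.46, Cldn4 by 3.29 ± 0.48, the membrane protease gene St14 by 3.53 ± 0.43 and the aldo-keto reductase gene Akr1c13 by 1.43 ± 0.18 (adjusted p = 0.380 for each). The epithelial list had 10 of 14 members positive, and 5 passed higher when adjusted over the list alone, which were Cldn4, Epcam, Cldn7, Ocln and Esrp1, named after their values were seen. Of the proliferation genes, 1 passed lower over the list alone, the cyclin gene Ccna2. In the heart-free libraries, 1 per clone, the epithelial score of c4 minus that of c3 was 0.98 in the yfp_6499c3 and yfp_6499c4 pair and 1.17 in the yfp_6556c3 and yfp_6556c4 pair. In the same pairs, c4 minus c3 was 0.50 and -0.49 for the class II score, 0.47 and -1.56 for pan-leukocyte markers, 0.55 and -2.04 for macrophage markers, and -0.46 and -2.43 for fibroblast markers. Positive fold changes in heart-free libraries were found for 4 of 7 class II, 1 of 10 pan-leukocyte, 0 of 12 macrophage and 0 of 11 fibroblast genes, and over all libraries for 5, 2, 3 and 10 of them. The type I interferon list had 0 of 24 members positive over all libraries, with c4 minus c3 at -1.49 and 0.04 in the same pairs. Skeletal muscle markers had a median log2 difference of 3.60 over all libraries and 0.12 in heart-free ones. The heart sum of the heart-bearing library was 4718 and 4748 CPM in yfp_6499c4 and yfp_6556c4, and 152 and 568 CPM in yfp_6499c3 and yfp_6556c3. The libraries at 4718 and 4748 CPM were among the closest pairs of all, at a chi-square of 3.83 per degree of freedom. Esrp1 was at 13.4 and 16.3 CPM in them, and at 2.31 and 2.21 CPM in the heart-free libraries of the same clones. Epcam was at 115 and 130 CPM, against 433 and 88.0 CPM. Of 16045 genes tested with edgeR, 0 were called and 1505 had an unadjusted p under 0.05, while DESeq2 called 286 higher and 168 lower. The count at an unadjusted p under 0.05 ran from 758 without yfp_6499c3 tumour 2 to 2945 without yfp_6556c4 tumour 2. Each line had 1 clone per class, so these p-values describe the spread between libraries. Where libraries of different clones resemble each other, that spread and the standard errors may be too small.

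The direction of class differences in the other lines was compared with that within these 2 lines. A fit without them, on 7 low and 4 high clones, called 0 genes, so the share of called genes could not be given. Of the 500 genes with the smallest p in each direction there, 68.3% had the same sign within the 2 lines. In heart-free libraries that share was 52.0%, with 36.4% for genes higher in T cell high clones and 67.6% for genes lower.

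The 2 intermediate clones differed from the low clones in 1 gene and from the high clones in 0. By their names, yfp_7160c5 was a sister of the high clone yfp_7160c2, and yfp_6422c5 of the low clone yfp_6422c1. Differences between these classes can therefore not be told apart from those between parent lines. H2-M2, a non-classical MHC class I gene (ENSMUSG00000016283, chromosome 17, 37480851 to 37483552), was at 8.03 CPM in intermediate clones, 2.64 ± 0.854 in high and 0.615 ± 0.252 in low clones, and rose by 3.70 ± 0.52 against low (adjusted p = 0.0358). Its level was 14.4 CPM in yfp_7160c5 and 1.63 CPM in yfp_6422c5, so the call rests on yfp_7160c5. Epithelial genes against low clones were Epcam at 2.45 ± 0.91, Cldn7 at 2.56 ± 0.69 and St14 at 3.54 ± 0.94, which did not pass. Of 20028 genes, edgeR called 1 higher and 0 lower, with 1009 at an unadjusted p under 0.05, and DESeq2 called 12 higher and 6 lower. Without yfp_6422c5 the count was 98 higher and 1 lower, without yfp_7160c5 it was 0, and in heart-free libraries it was 0 with 1134 at an unadjusted p under 0.05. The 1 lower gene without yfp_6422c5, named after its value was seen, was 9430020K01Rik. For high against intermediate clones, edgeR and DESeq2 each called 0 genes, with 414 and 526 at an unadjusted p under 0.05, and with 1568 for edgeR without yfp_7160c5.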

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

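Tests of the heart and liver transcripts, of the epithelial genes and of the direction within parent lines were chosen after the result was seen, as were all tests in heart-free libraries. In all, 222 groups of clones were examined for a value far from the rest, and 22 held one, where chance alone gives about 1 in 20 groups. Values that share a clone or a gene list are not separate evidence.

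The gap to the nearest clone was divided by the range of the class. Clone yfp_6419c4 lay lowest among T cell low clones, by a gap of 0.628 of the whole range for the pan-leukocyte score, 0.505 for macrophage markers, 0.527 for adipocyte markers, 0.522 for MHC class II presentation and 0.515 for p53 targets. For single genes the gaps were 0.567 for H2-Ab1, 0.597 for H2-Eb1, 0.530 for Cd74, 0.517 for H2-DMa, 0.639 for H2-Aa and 0.564 for Serping1. This clone had 1 library, which was heart-free, and was the only low clone with no heart-bearing library. Among heart-free libraries it was not the lowest low clone for pan-leukocyte (1.15) or macrophage markers (2.15), where yfp_6419c5 was at 0.889 and 1.73. It stayed lowest for class II (1.19, with 1.31 in yfp_6694c2) and for p53 targets (4.39, with 4.49 in yfp_6419c5). Clone yfp_2838c3 lay apart among high clones for Rbpj (lowest, 0.640), Zzz3 (highest, 0.730) and Pdx1 (lowest, 0.678). Clone yfp_6556c4 did so for H2-M2 (lowest, 0.8286), Pde7a (lowest, 0.719) and the cholesterol synthesis score (highest, 0.7098), and yfp_6620c1 for Irf1 (lowest, 0.647). Among low clones, yfp_6694c2 lay lowest for Krt7 (0.688), yfp_2699c4 highest for Myc (0.626), and yfp_6421c2 highest for B2m (0.507) and H2-K1 (0.522). Between the 2 parent lines that held both classes, 0 of 16045 genes were called for a different class effect in an edgeR interaction test, with 591 at an unadjusted p under 0.05 and DESeq2 not run for it. This cannot show that the lines agree, since the simpler test within lines recovered 1% and 44% of simulated changes of log2 1 and 2. In heart-free libraries, c4 minus c3 was 0.55 and -2.04 for macrophage markers, and 0.98 and 1.17 for the epithelial score.

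Heart transcripts were also present in 2 of the libraries with no class, at 2123 CPM in yfp_6883c1 and 3780 CPM in yfp_6883c4, and were at 0.0268 CPM in yfp_7062c3. A candidate explanation is RNA of one shared source mixed into 19 libraries, since the log2 ratio of liver to heart transcripts had an SD of 0.0657 over them while their level ran from 152 to 4893 CPM. Host cells carried through the sort of each tumour would give ratios that vary between tumours, which this SD argues against. When and how such RNA entered was not tested, and no biological explanation was tested, since the design gives none.

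Epithelial genes were higher in T cell high clones, by 0.86 in score, without passing over the lists. Mixed heart and liver RNA as the cause is argued against by the difference of 1.09 in heart-free libraries. Dilution of low clones by other cells would lower all tumour genes alike, and the epithelial score minus the pancreatic duct score differed by 0.770 (exact permutation p = 0.00666). The epithelial list was picked for its small p in the same clones, so this p is no separate support. The duct list also holds Cftr and Agr2, which were higher in high clones over all libraries. In heart-free libraries, pan-leukocyte and macrophage scores differed by 1.36 and 1.35 and fibroblast markers by -0.19, without passing. The fibroblast difference depended on yfp_6555c3, at a score of 7.44. The other high clones were at 1.60 to 3.00, and low clones at 1.94 to 5.59 with a mean of 3.47. Fold changes of the fibroblast markers were positive for 9 of 11, against the sign of the score. Dilution of low clones by fibroblasts is therefore not excluded by this score. A difference in cell state that goes with T cell class may remain, as a hypothesis from the data it was tested on, and the dependence on single clones and chance among lists stay open.

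MHC class II genes were higher in T cell high clones in heart-free libraries, by 2.16 in score, and the pan-leukocyte score by 1.36, but neither passed over the lists (adjusted p = 0.108 and 0.4665). Leukocytes carried through the sort may account for part of this: over 14 clones the 2 scores had a Pearson r of 0.757 (permutation p = 0.00177) and a Spearman rho of 0.798 (permutation p = 0.00114), and r was 0.629 without the 2 clones farthest from the median. Within classes r was 0.806 over 6 high and 0.628 over 8 low clones. Beside the pan-leukocyte score the class difference was 1.32 (permutation p = 0.0160), against 2.16 before, and in yfp_7160c2 the class II score of 5.22 was above every low clone at a pan-leukocyte score of 2.0. Class II expression by tumour cells and by leukocytes cannot be told apart, because the difference left lay between the bounds set before it was computed for and against leukocytes as the cause, and 1 clone is too few to exclude them.

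Chance could not be excluded for the counts of genes at an unadjusted p under 0.05, or called by DESeq2, between T cell high and low clones. With edgeR, 5 of 100 splits of the clones, the real one included here and in each share that follows, gave as many genes at an unadjusted p under 0.05 as the real 2176, up to 3378, and in heart-free libraries 8 of 100 for the real 2095, up to 3607. For the genes called, the real count was 0, which all 100 splits must reach, so this comparison decides nothing. The highest other count called was 3, and 662 in heart-free libraries, where the next were 321 and 195. Such counts point to a structure of the clones, which was not tested. The splits treat clones of one parent line as exchangeable, which they may not be. The low sister clones yfp_6419c1, yfp_6419c4 and yfp_6419c5 lay lowest on the second principal component of the heart-free libraries, at -63.8, -67.3 and -78.7. The split with 662 calls set yfp_2699c4, yfp_2838c3, yfp_6499c3, yfp_6556c3, yfp_6556c4 and yfp_6694c2 against the rest, and that with 321 calls was the real one with yfp_6499c3 in place of yfp_6556c4. With DESeq2, 5 of 50 splits called at least the real 123 genes, up to 2909. Within parent lines there were 18 splits, too few for a share under 0.05. Of these, 4 gave as many genes at an unadjusted p under 0.05 as the real 1505, and the highest other, 3591, was the split by heart transcripts. With heart transcripts as a further block, the real split gave 2130 such genes and 0 calls. For the direction of genes ranked elsewhere, computed here on log2 CPM, 7 of 18 splits gave as high a share as the real 65.1%, up to 81.0%, and the split by heart transcripts gave 72.1%.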

How the results depend on the processing

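Settings that divide libraries by heart transcripts, and all settings of the heart-free comparison, were chosen after seeing the data, and the others before.

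Between T cell high and low clones, edgeR under each other scaling, filter, threshold and covariate, and limma, called 0 genes, with 1273 to 3210 at an unadjusted p under 0.05. DESeq2 called 80 higher and 43 lower. With counts summed per parent line and class, edgeR called 0 genes, with 2523 at an unadjusted p under 0.05 and a smallest adjusted p of 0.308. With each library as a replicate, 4 were higher (Cldn7, Trpv4, Cited4, Gal3st2) and 5 lower (Tex2, Vps54, Ell2, Rbpj, Ube3c), and libraries of a clone are not independent there. With heart transcripts as a block per library, 58 were higher and 69 lower. With a clone left out in turn, 0 to 12 were higher and 0 to 4 lower, with 12 and 4 without yfp_2838c3. In heart-free libraries, DESeq2 called 180 higher and 119 lower, and Tex2 was the 1 lower gene both per library and at an adjusted p under 0.1. Leaving out a clone gave 0 to 19 higher and 0 to 18 lower there. The cause was not tested.

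Deviations of libraries that share tumour number 1 correlated by 0.596 on average (-0.114 to 0.898), of number 2 by 0.248 (-0.715 to 0.702) and of different numbers by -0.252. Not every pair was above 0.1, so the numbers were not taken as pairs, and number 1 went with heart transcripts in 18 of 19 libraries. With the tumour number as a block, 3 genes were higher (Cited4, Gstt2, AI661453) and 5 lower (Tex2, Vps54, Ell2, Rbpj, Ube3c).

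Camera with a preset correlation called 11 lists higher and 4 lower, and in heart-free libraries 7 higher and 1 lower, and with an estimated correlation 0 in each. Leaving out a clone gave 0 to 1 list higher in each set. With clones averaged per parent line and class, the exact permutation test called 0 lists, with a smallest adjusted p of 0.136. Within parent lines, DESeq2 called 286 genes higher and 168 lower, and a trend over all lines with 2 classes called 2 higher, Akr1c12 and Akr1c13. The share of genes with the same direction within parent lines was 52.0% in heart-free libraries. This share was planned for genes called elsewhere, of which there were 0. A set of 500 genes per direction, chosen after the result was seen, took their place. Against low clones, intermediate clones gave 12 higher and 6 lower genes with DESeq2 and 0 in heart-free libraries, and 0 to 98 higher and 0 to 1 lower with a clone left out, where the lone intermediate clone was assumed to vary like the others.

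Over 211 named genes, 60 of 6892 values under other settings passed, in 21 genes, and over 39 lists, 16 of 892, in 15 lists. None that passed had the opposite sign, but among values that did not pass, 432 in 106 genes and 50 in 19 lists did. These tallies leave out other methods and left-out clones within heart-free libraries, where further values passed. Among lists, lymphocyte attractants and the interferon gamma response passed only there. Scaling by library size moved the median log2 fold change by 0.06. The library of fewest counts, with 7638130, was summed with 3 others of yfp_2699c4, and what depth limits was not tested.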

Other observations

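Tests in this part were chosen after the data were seen. The clones differed in transcripts of the sex chromosomes, and the heart-bearing libraries held both kinds. Xist, which silences an X chromosome in female cells, ranged from 0.161 to 2533 CPM over the 20 heart-free libraries, and the Y-linked gene Ddx3y from 0 to 41.3 CPM. In yfp_7160c2 (T cell high), yfp_7160c5 (intermediate) and yfp_6555c3 (T cell high) the heart-free library held Ddx3y at 38.9, 41.3 and 16.9 CPM. In heart-free libraries of low clones it was at most 2.15 CPM, in yfp_6421c2. Y-linked transcripts were therefore uneven between the classes, and no fit held them as a covariate. In yfp_2838c3, Ddx3y was at 0 in the 3 heart-free libraries and at 32.1 CPM in the heart-bearing one. All 19 heart-bearing libraries held Ddx3y, at 4.55 to 61.6 CPM, and Xist, at 22.3 to 1232 CPM.

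Liver genes were also present without heart genes. The heart-free library of yfp_6419c1 held the albumin gene Alb at 118.7 CPM and the fibrinogen gene Fga at 44.9 CPM. In yfp_2838c3, Alb was at 9.98, 14.8 and 36.5 CPM in the 3 heart-free libraries, in yfp_6422c5 at 24.1 CPM and in yfp_6499c3 at 19.1 CPM, with Fga at 0.384 CPM or less in these 5. In yfp_6419c5, Alb was at 6.82 CPM and Fga at 1.12 CPM, and in the other heart-free libraries Alb was at most 0.726 CPM. Of the 2 intermediate clones, yfp_7160c5 had an epithelial score of 8.28 and a class II score of 7.19 in its heart-free library, above every high and low clone. The other, yfp_6422c5, had 5.12 and 1.64, and its pan-leukocyte score was 0.48 against 5.26 in yfp_7160c5. In yfp_7160c2, the high sister of yfp_7160c5, the epithelial score was 7.76, the highest of the high clones, and the class II score 5.22.

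Among libraries with no class, the epithelial adhesion gene Epcam was at 26.8 CPM in yfp_6883c1, 86.9 CPM in yfp_6883c4 and 31.0 CPM in yfp_7062c3. The neutrophil attractant gene Cxcl1 was at 12.5, 21.5 and 14.9 CPM in the same order.

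The first principal component of the heart-free libraries, which held 25.5% of the variance, averaged -31.9 ± 46.1 over 6 high and 12.9 ± 20.8 over 8 low clones (2-sided exact permutation test, p = 0.0320). The high clones lay apart from each other on it. Of these, yfp_6555c3, yfp_7160c2, yfp_6499c4 and yfp_6620c1 were at -79.2, -58.0, -56.6 and -50.1, and yfp_2838c3 and yfp_6556c4 at 25.5 and 26.9, within the range of the low clones of -8.44 to 48.1. Leukocyte transcripts differed along it. In yfp_2838c3, the library at -6.65 held the leukocyte gene Ptprc at 58.6 CPM, and those at 46.8 and 36.4 held it at 6.03 and 4.80 CPM. The intermediate clones yfp_7160c5 and yfp_6422c5 were at -93.4 and 51.5, with Ptprc at 73.6 and 1.82 CPM, while yfp_7160c2 at -58.0 held it at 3.26 CPM.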
